A study of Mus musculus with 8 samples.

How the data were processed

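The series holds ATAC-seq libraries, in which a transposase cuts and tags open chromatin, from mouse bone marrow. Per the labels, 8 libraries were made from cells that carry cKit and were depleted of lymphoid and erythroid cells by sorting, a fraction rich in stem and progenitor cells. The labels give 4 libraries as acute myeloid leukemia (AML) and 4 as normal. Of the AML libraries, 2 are heterozygous for a deletion of the URE (the upstream regulatory element of Spi1) and for Tet2, and 2 are URE-heterozygous with both Tet2 copies disrupted. The normal libraries are 1 each of wild type, URE heterozygous, Tet2 heterozygous and Tet2 knockout. By the lanes recorded for the libraries, the Tet2 heterozygous and Tet2 knockout normal libraries lie in lane 8, which holds no AML library. The other libraries lie in lanes 6 and 7, so lane and leukemia are partly mixed if those normal libraries were compared.

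The values analysed are the authors' own comparison of leukemic with non-leukemic cells, named for low PU.1, the protein that Spi1 encodes. Which libraries stood on each side is not given in the sources used here. The only normal library labelled with the URE deletion is 1 heterozygote, so the non-leukemic side may rest on 1 library, and every fold and adjusted p depends on that unknown. Per the submitters' processing notes, the reads were processed against GRCm38 (mm10), and the tools named there are Bowtie2 2.4.1, SAMtools 1.10.2 and Genrich 0.6. The title of the authors' deposited table names csaw, a window-based method for differential accessibility. Its settings, the normalization and the read filters are not given in the sources used here, nor is any shift of reads for the transposase's cut. The deposited log2 fold change per region is the authors' leukemic over non-leukemic value. A deposited log2 average abundance per region is the authors' measure of read level, a reading of the column that rests on its position and range. The authors' deposited p-value per region comes with an adjusted p-value, which equals a Benjamini-Hochberg adjustment of the p-values over all regions to within 2.39e-15.

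The full table holds 160978 regions on chromosomes 1 to 19 and X, 149 to 7216 bp wide, with a lowest log2 abundance of -3.01. The authors also deposited a more accessible set of 2002 regions, a less accessible set of 1961 and an unchanged set of 19123. Each was found to equal the regions of the full table with an adjusted p-value under 0.001 and the matching sign, or over 0.9. The words changed, rose and fell refer to the sets at 0.001. No per-library values were used, so depth per library is unknown, no interval could be set on any fold change, and no test across replicate animals was made. Coordinates are printed as deposited; whether starts count from 0 or 1 is not given in the sources used here.

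Genes came from a RefSeq table of GRCm38.p6 with 49997 genes, 21900 of them protein coding. That table gives the extent of each gene without strand or exons, so the planned distances to transcription start sites were replaced. Each region centre was given to the gene whose extent was nearest, within 100 kb, which assigned 158996 regions (98.8%). A region centre within 1 kb of either end of any gene was called a gene end, other centres inside a gene were called gene interior, and the rest intergenic. A planned comparison of 30 sequence motifs was not run, since no genome sequence was used here.

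More against less accessible counts were compared with an exact binomial test. Location was compared with the authors' unchanged set, and chromosomes with all other chromosomes, by two-sided Fisher's exact tests. For 18 gene lists fixed before the data were examined, members with at least 1 changed region were compared with all other genes that had a tested region, by Fisher's exact test. A permutation test moved the calls over regions 100000 times while keeping the number of regions per gene, and was repeated within 10 equal classes of abundance and, after the data were seen, with calls at an adjusted p under 0.05. Benjamini-Hochberg adjustment was applied within each family, and 0.05 was the threshold. Folds at gene ends and elsewhere were compared with a Mann-Whitney rank sum, with a p-value from 100000 permutations of the regions. Regions are not independent samples, so all of these tests describe the authors' lists and not variation between mice. A scan for the stretch of each chromosome whose mean fold differed most from the rest used blocks of 20 regions with values limited to 1.5 in size, and was chosen after the data were seen.

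The scan and the tests were tried on simulated data for this comparison. A block lowered by 1 on the log2 scale among the 12588 regions of chromosome 2 was recovered in 50 of 50 draws, and the highest statistic with no block was 4.47. That simulation leaves out the likeness of neighbouring regions, and 13 of the 19 other chromosomes exceeded it. Calls shuffled over the 160978 regions gave 43 false calls among 720 Fisher's exact tests of the lists and 0 among 720 permutation tests. Genes with many regions collect calls by chance, which Fisher's exact test ignores. The permutation test makes the same shuffle itself, so its 0 says nothing about calls that gather in neighbouring regions. The stem and progenitor list alone gave 15 false calls in 40 such Fisher's exact tests. Both tests recovered the erythroid list, which holds 175 regions, in 20 of 20 draws when 12 of its members were given a call. No such trial was made for the stem and progenitor list, which holds 622 regions, so the power there is unknown. With no difference planted over 21125 regions, the location test called 12 of 200 draws.

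Genes named in the text were chosen by a rule fixed before the data were examined. It takes Spi1 and Tet2, per direction the 8 genes with the most changed regions and the 6 regions of largest fold, and per list up to 4 members of the main direction and 2 of the other. Lists with 5 or fewer changed members in a direction are named in full where space allows. Predicted genes with Gm numbers count in the ranks and are left out of the prose in favour of the next named gene. A few genes that the rule takes are not reported here. Alternatives covered the threshold, the gene assignment, the background, the sex chromosome, region width and the segment of chromosome 2. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.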

Results

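Chromatin accessibility was measured by ATAC-seq in cKit-positive mouse marrow cells sorted to deplete lymphoid and erythroid cells, a fraction rich in stem and progenitor cells. The 8 libraries comprised 4 from mice with acute myeloid leukemia and 4 from mice without it. Every leukemic library was labelled heterozygous for a deletion of the URE, a distal enhancer of Spi1, together with loss of 1 or both copies of Tet2. The authors' comparison of leukemic with non-leukemic cells with low PU.1 gave 1 log2 fold change per region over 160978 regions. No normal library carried both the URE deletion and Tet2 loss, so leukemia and the double genotype cannot be told apart, and only 1 normal library carried the URE deletion. No values per library were used, so the spread between mice is unknown for every value printed.

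The comparison asks which regulatory regions differ in accessibility between leukemic and non-leukemic cells with reduced PU.1, and the engineered loci were examined before all others. Spi1, which encodes the myeloid transcription factor PU.1, lost accessibility along its upstream part. In the authors' deposited table, the region at chromosome 2, 91080912 to 91081419, had a log2 fold change of -7.30 (adjusted p = 1.26e-06), the lowest of all 160978 regions. The neighbouring region at 91082812 to 91083646 stood at -6.21 (adjusted p = 7.23e-09) in the authors' deposited table. Both lie in the stretch upstream of the main Spi1 promoter where the URE is known to be. Tet2, which encodes a dioxygenase that oxidises 5-methylcytosine in DNA, had 0 changed regions among 31 within 100 kb.

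Within 100 kb of Spi1, 6 of 40 regions fell and 0 rose, and the 6 all lay within 20 kb of the gene. Of the 6, the region at 91069960 to 91070759 was assigned to Slc39a13. It stood at -1.05 in the authors' deposited table, close to the median of -0.95 over the 40 regions. Next to the 2 most reduced regions, the region at 91078339 to 91078801 had a log2 fold change of -3.55 in the authors' deposited table. The region at 91096409 to 91097272, at the main promoter, stood at -2.14 (adjusted p = 2.93e-04) in the authors' deposited table. At the annotated end of Spi1 away from the URE, the regions starting at 91112552, 91113394 and 91115121 had values of 0.96, 0.82 and 1.85 in the authors' deposited table, with adjusted p of 0.0768, 0.176 and 0.0017. At Tet2 the lowest adjusted p within 100 kb was 0.00635 in the authors' deposited table, and 2 regions lay under 0.05. The Tet2 gene body and 20 kb on either side held 14 regions with a median log2 fold change of -0.36.

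**Figure D1:**
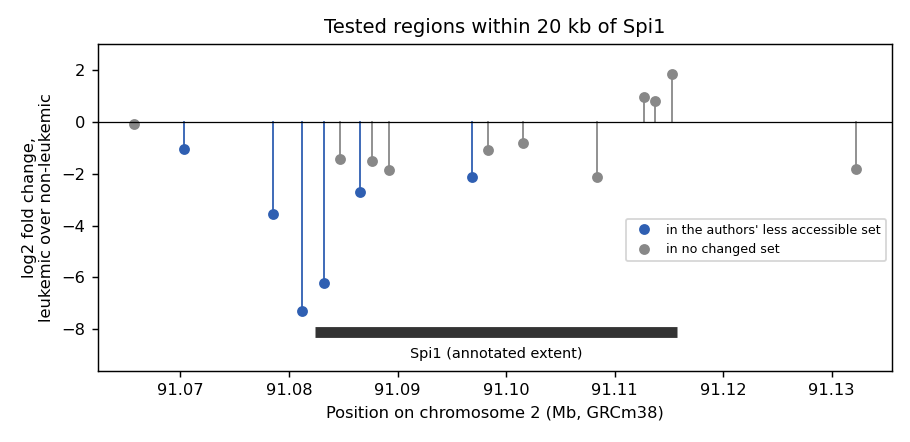
Log2 fold change (leukemic over non-leukemic, vertical axis) of the 17 tested regions within 20 kb of Spi1 against position on chromosome 2 in Mb (GRCm38). Values are from the authors' deposited table; blue marks the 6 regions in the authors' less accessible set, grey the others, the bar is the annotated extent of Spi1, and the lowest points are -7.30 and -6.21.

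Spi1 lay within a long stretch of chromosome 2 in which accessibility was lower in leukemic cells at regions of every kind. From 53.7 to 158.2 Mb, 6840 regions had a median log2 fold change of -0.99, with quartiles of -1.62 and -0.45. The median over the other regions of chromosome 2 was 0.10. The stretch held 370 regions that fell and 13 that rose. Cd44, a receptor for hyaluronan, had 8 regions that fell, and Cd82, a tetraspanin of stem cells, had 6, out of 20 and 14 tested. The Lmo2, Procr, Hdc, Il1b and Asxl1 genes also lie in it and had 1 or 2 reduced regions each. Regions at gene ends of Pcna, the DNA replication clamp gene, and E2f1, a cell cycle transcription factor gene, stood at -0.94 and -1.05 in the authors' deposited table.

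The scan statistic for this stretch was 20.6, against 8.53 for the highest of the other chromosomes, a rise of 0.55 in the median over 7 Mb of chromosome 10. The 19 bins of 5 Mb that lay inside it and held at least 50 regions had medians from -1.12 to -0.87. The 480 other bins, those across its edges included, ranged from -0.83, on chromosome X, to 0.72. The scan picked the stretch from these same folds, so lower medians inside it were built in. The scan was chosen after the data were seen, and 13 of the 19 other chromosomes exceeded the highest statistic of simulated unordered values, 4.47, so the other chromosomes are the stricter reference.

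**Figure D2:**
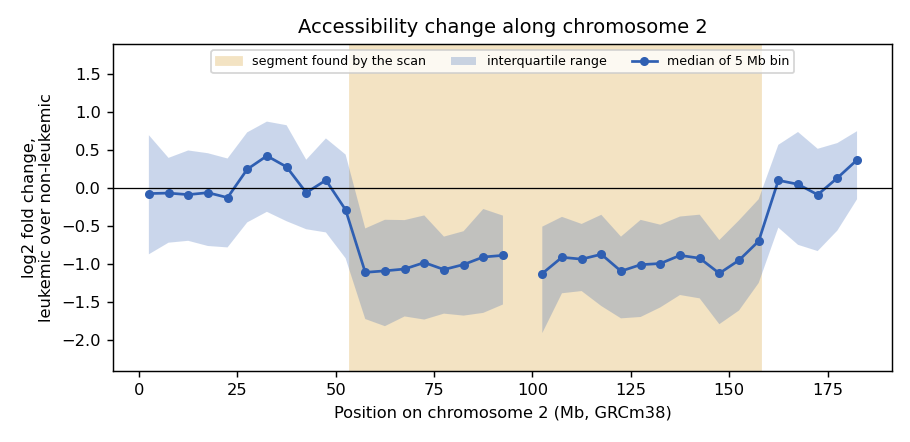
Median log2 fold change (leukemic over non-leukemic, vertical axis) of the regions in each 5 Mb bin of chromosome 2 against position in Mb (GRCm38), for bins with at least 50 regions; the blue band is the interquartile range over regions. The shaded stretch from 53.7 to 158.2 Mb had a median of -0.99, against 0.10 for the rest of the chromosome.

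Across the genome 2002 regions rose and 1961 fell in leukemic cells. Tmem108, a transmembrane protein gene, had gains at 7 of 38 tested regions. Baz1a, which encodes a subunit of chromatin remodelling complexes, had 6. Cdk6, a kinase of the G1 phase of the cell cycle, had 5, as did Afap1, F13a1, Flt1 and Wwox. Gains at Cdk6 ran from 1.76 to 3.01 on the log2 scale and those at Tmem108 from 2.14 to 3.90 in the authors' deposited table. Wwox, with 104 tested regions, also had 1 region that fell.

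Losses gathered at Sgms1, which encodes a sphingomyelin synthase, with 9 of 57 regions from -1.68 to -4.59 in the authors' deposited table. Retreg1, a receptor for autophagy of the endoplasmic reticulum, and Med12l, a Mediator subunit gene, had 7 each. Syne1, which links the nucleus to the cytoskeleton, and Agpat4, an acyltransferase gene, had 5 each, as did Spi1. Outside the chromosome 2 stretch Entpd1, which encodes the ectonucleotidase CD39, also had 5 regions, from -2.54 to -4.39 in the authors' deposited table. None of the regions at Sgms1, Retreg1, Med12l, Syne1, Agpat4 or Entpd1 rose.

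Among the largest gains, a region inside Dlc1 reached 5.33 (adjusted p = 1.44e-06) in the authors' deposited table. A region 5.7 kb from Pura, a nucleic acid-binding protein gene, reached 4.69 (adjusted p = 7.23e-09) in the authors' deposited table. Regions inside Atxn1, Colec12 and Clstn3 followed at 4.39, 4.38 and 4.30 in the authors' deposited table. The largest loss after Spi1 was -7.19 (adjusted p = 6.21e-04) at a region 5.9 kb from Slc30a4, a zinc transporter gene, in the authors' deposited table, at a low log2 abundance of -1.85. St3gal5, the ganglioside GM3 synthase gene, stood at -5.13 and Retreg1 at -5.03 in the authors' deposited table, both outside the chromosome 2 stretch.

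The near-even split of 50.5% gains (exact binomial p = 0.525) moved to 55.6% (exact binomial p = 3.10e-11) once the chromosome 2 stretch was left out, with 1989 gains and 1591 losses. At an adjusted p under 0.05 it was 46.4% of 27674 regions, and 49.9% without the stretch (12763 gains and 12840 losses, exact binomial p = 0.635). Losses lay in more abundant and wider regions than gains, with median widths of 752 and 346 bp. The 32196 most abundant regions, 1 of 5 equal classes, held 1694 of the losses and 832 of the gains.

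Stem and progenitor genes were the list with the most members near losses. Of 33 members with tested regions, 12 had at least 1 region that fell and 3 had at least 1 that rose, with 20 and 7 regions in all. Meis1, a homeobox gene of stem cells and leukemia, had 3 losses, the deepest at -4.21 (adjusted p = 4.76e-07) in the authors' deposited table. Cd34 also had 3, between -2.48 and -2.89, and the ETS factor gene Erg had 2, at -3.84 and -2.89, in the authors' deposited table. Msi2, an RNA-binding protein gene of stem cells, had 2. Runx1, a core transcription factor of blood formation, had 4 gains and 2 losses, and Fli1 had 2 gains.

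The stem and progenitor count gave an odds ratio of 10.9 (Fisher's exact test, adjusted p = 1.11e-06 over 36 tests), with 10 members outside the chromosome 2 stretch. That test ignores that these genes hold many regions, 622 in all; with calls permuted over regions 6.09 members were reached by chance (permutation test, adjusted p = 0.335). Adjusted over the list alone, 24 of its regions fell and 9 rose at 0.001. By permutation at the authors' threshold, none of the 36 tests over the 18 lists had an adjusted p under 0.05, and the other 35 were not called by Fisher's exact test either. At an adjusted p under 0.05, 19 stem and progenitor genes lay near losses, with 19.4 reached by chance (permutation test, adjusted p = 1). Near gains there were 8, with 18.4 reached by chance (permutation test, adjusted p = 7.20e-04).

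Granulocyte genes showed both directions. Of the genes of primary granule proteins, Ctsg had 2 gains, at 2.80 and 2.13, and Mpo and Elane had 1 each, at 2.33 and 1.82, in the authors' deposited table. Gfi1, a repressor needed for neutrophil formation, had 2 gains and Hp, the haptoglobin gene, had 1. Ltf, Retnlg, Fpr1 and Itgb2l, genes of later neutrophils, each had 1 region that fell, with Fpr1 at -3.39 in the authors' deposited table. Prtn3, also a primary granule protein gene, had 0 changed regions, as did other genes of later neutrophils such as Camp, Lcn2, Mmp9 and Cxcr2. No grouping by stage was fixed beforehand or tested. The list had 5 of 30 members near gains, with 1.63 reached by chance (permutation test, adjusted p = 0.732), or 2.64 at matched abundance. It had 4 near losses, with 1.61 reached by chance, or 3.96 at matched abundance.

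Among monocyte and macrophage genes F13a1, the factor XIII A chain gene of monocytes, had 5 gains, and Irf8, Ccr2 and Ly86 had 1 each, from 2.52 at Ly86 to 3.14 at Ccr2 in the authors' deposited table. Tlr2 had 2 losses, and Fcgr1 and Adgre1 1 each, with Adgre1 at -3.34 in the authors' deposited table. Known PU.1 targets had 5 of 32 members near losses, among them Spi1, Il1b, Fcgr1 and Flt3, and 3 near gains, Fes, Irf8 and Ncf1. Only 2 of those 5 lay outside the chromosome 2 stretch, Fcgr1 and Flt3. At an adjusted p under 0.05, 20 PU.1 targets lay near losses (odds ratio 4.91, Fisher's exact test, adjusted p = 1.84e-04), with 14.9 reached by chance (permutation test, adjusted p = 0.297) or 19.2 at matched abundance (permutation test, adjusted p = 0.977). Outside the stretch the count was 17 of 29, with 12.1 and 15.9 reached by chance.

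Megakaryocyte genes had losses at 4 of 20 members, Itga2b, Itgb3, Vwf and F2rl2, and 0 gains (permutation test of losses, adjusted p = 0.75). B-cell genes had losses at 3 of 22, Bach2, Bank1 and Dntt, with Bach2 at -3.05 and -2.85 in the authors' deposited table. Dendritic cell genes had losses at 4 of 21, Zbtb46, Flt3, Xcr1 and H2-Aa, and a gain at Runx2. Mast cell and basophil genes had losses at Cd200r3, Hdc and Il1rl1 and a gain at Mcpt8. The erythroid, T or NK cell and B-cell lists mark cells that the sort should deplete. Erythroid and T or NK cell genes had 0 changed regions at 27 and 26 members, where 2.07 and 2.17 members near gains were reached by chance.

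Leukemia genes had gains at 6 of 32 members, Runx1, Ptpn11, Zbtb16, Etv6, Cbl and Nf1, with 1 region near Ptpn11 at 4.16 in the authors' deposited table. Losses lay at Meis1, Runx1, Asxl1 and Flt3, and 5.55 members near gains were reached by chance (permutation test, adjusted p = 1). Chromatin modifier genes had gains at Kdm1a, Arid1a, Tet3 and Kmt2c and losses at Asxl1 and Kdm2b, with Kdm1a at 3.38 in the authors' deposited table. Cell cycle genes had gains only at Cdk6 and losses at Rb1, E2f1 and Pcna. Adhesion and homing genes had 16 losses, all in the chromosome 2 stretch at Cd44, Cd82, Itga4 and Itgav, and gains at Itgb7, Ccr2, Cxcr4 and Icam2.

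Endothelial and stromal genes had 5 gains at the VEGF receptor gene Flt1 and 1 at Runx2, and losses at Eng, Kdr and Vwf. Immediate early genes had losses at Dusp2, Klf6 and Atf3, and inflammation genes at Nfkb1, Cxcl2 and Il1b, with 0 gains in either list. Of these, Dusp2 and Il1b lie in the chromosome 2 stretch. Among housekeeping genes 1 of 25 had a gain, at Hprt. Adjusted over the list alone, 23 adhesion and homing regions fell and 10 rose, 16 PU.1 target regions fell and 6 rose, and 11 leukemia gene regions fell and 12 rose. Adjusted over all regions, 11 PU.1 target regions fell and 3 rose, of which 2 losses and 3 gains lay outside the chromosome 2 stretch. Adjusted over the list alone, 10 granulocyte regions rose and 6 fell, and 7 megakaryocyte regions fell and 1 rose.

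**Figure D3:**
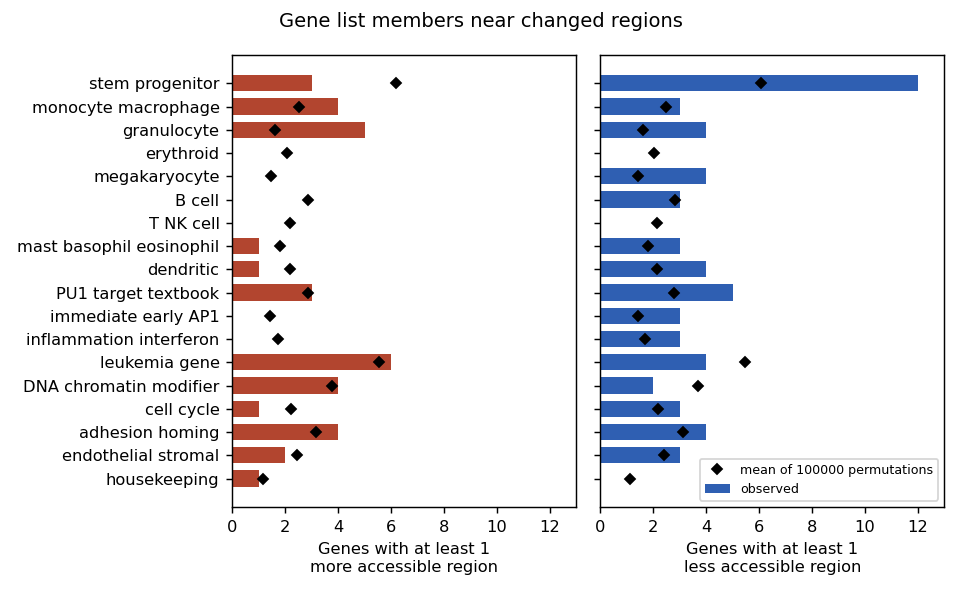
Number of genes (horizontal axes) of each of the 18 lists with at least 1 region in the authors' more accessible (left) or less accessible set (right). Bars are observed counts and diamonds the mean of 100000 permutations of calls over regions; the stem and progenitor list had 12 genes near losses against a mean of 6.09.

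Gains inside genes, as at Cdk6, Runx1 and Tmem108, were more frequent than unchanged regions there at the authors' threshold. Of the gains, 57.5% were in gene interiors against 53.0% of the unchanged set (odds ratio 1.20, Fisher's exact test, adjusted p = 6.73e-04), and 27.3% were intergenic against 30.6%. Losses were in gene interiors at 52.6%, and 18.1% of them were at gene ends, such as those of Tal1 and Cd34, against 16.4% of unchanged regions (Fisher's exact test, adjusted p = 0.12). The call for gains in gene interiors was lost with gene ends widened to 3 kb (odds ratio 1.07, Fisher's exact test, adjusted p = 0.271), at the stricter threshold of 0.0001 (1.18, adjusted p = 0.151) and at 0.05 (1.01, adjusted p = 0.552). The unchanged regions were far less abundant, with a median of -1.72 against 1.42 for losses. Against regions of matched abundance, chosen after the data were seen, gene ends had odds ratios of 0.606 among gains and 0.384 among losses, and interiors 1.34 and 1.47. The 24895 gene-end regions had a median log2 fold change of 0.19 and the 136083 others -0.02, a difference of 0.21 (permutation test of the Mann-Whitney rank sum over regions, p = 2e-05, the smallest it can give).

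With all regions, losses exceeded the rest of the genome only on chromosome 2, where 3.42% of 12588 regions fell (odds ratio 3.39, Fisher's exact test, adjusted p = 1.70e-84). Gains exceeded the rest on chromosomes 7, 8, 15, 17 and 19, with 2.24% on chromosome 8, which carries Wwox, Dlc1 and Zcchc14 (Fisher's exact test, adjusted p = 3.95e-12). Chromosome X had 18 gains and 35 losses among 3821 regions, with a median log2 fold change of -0.45. The split of gains and losses differed from the other chromosomes on 11 of the 20 chromosomes, a comparison that includes the chromosome 2 stretch. Without the stretch it differed on 5, chromosomes 1, 3, 8, 12 and X; gains exceeded the rest on chromosomes 8 and 19 alone, and losses on chromosome 1 (odds ratio 1.32, Fisher's exact test, adjusted p = 0.0233).

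**Figure D4:**
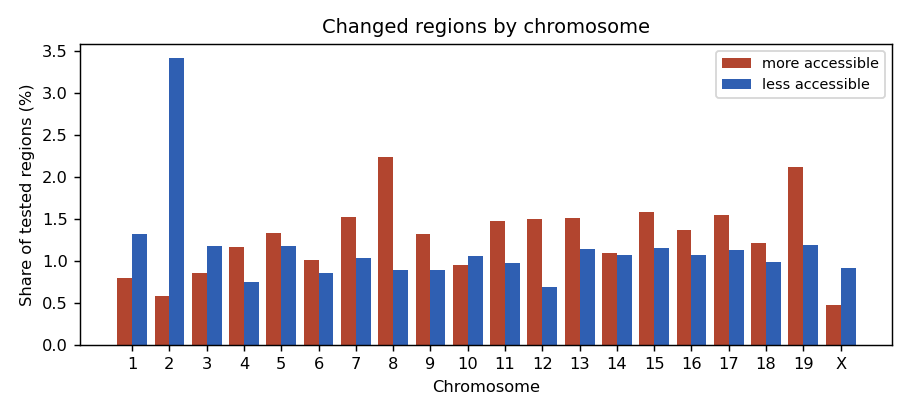
Share of tested regions (%, vertical axis) in the authors' more accessible (red) and less accessible (blue) sets on each chromosome. Chromosome 2 had 3.42% of its regions in the less accessible set, and chromosome 1, the next highest, 1.33%.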

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

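Leaving out a replicate was not possible without values per library, no paired analysis was possible because no values per library were used, and the motif alternatives and the fold of the best window were not run. Unknown depth limits every fold. The settings without the chromosome 2 stretch, at an adjusted p under 0.05, with matched abundance, with protein-coding genes for the lists and with distance to gene ends were chosen after the data were seen. A stricter adjusted p, under 0.0001, left 623 gains and 405 losses, 60.6% gains, 2 list tests called, interior odds ratio 1.18 among gains, no longer called, and 7 chromosomes called. An adjusted p under 0.05 gave 12849 gains and 14825 losses, which turned the split to 46.4% gains, with 10 list tests called, PU.1 target losses among them; with the chromosome 2 stretch also left out it was 49.9% (12763 gains, 12840 losses). Over all regions at 0.05, odds ratios among gains were 1.19 at gene ends, turned, and 1.01 in interiors, no longer called; among losses, 0.839 and 1.06, both turned. Without the stretch at the authors' threshold the split was 55.6% gains, 5 chromosomes were called and losses on chromosome 2 had an odds ratio of 1.01, since the stretch held most of them. Gene ends widened to 3 kb gave 1.19 among gains, turned, and 1.07 in interiors, no longer called; protein-coding genes gave 0.837 at gene ends among gains. All other regions as background gave 1.21 at gene ends among losses. With matched abundance, gene ends gave 0.606 among gains and 0.384 among losses, turned, and interiors 1.47 among losses, turned. Intergenic regions gave 1.01 among gains, close to no difference, and 1.49 among losses, turned. This background is the same set of all other regions, matched on abundance. Permutation over regions left 0 list tests, with the stem and progenitor losses at 1.97 times the chance number, or 1.91 within classes of abundance, which also left 0. Permutation at 0.05, chosen after the data were seen, called 2 tests, stem and progenitor gains and B-cell gains. At matched abundance it called 2, stem and progenitor gains and chromatin modifier losses. B-cell gains lay at 4 members, with 10.3 reached by chance (permutation test, adjusted p = 0.0241), or 9.65 at matched abundance (permutation test, adjusted p = 0.057). With the chromosome 2 stretch also left out, matched abundance kept the stem and progenitor and chromatin modifier calls. It then also called B-cell gains, dendritic cell gains and cell cycle losses (permutation test, adjusted p = 0.0454, 0.0439 and 0.0312), all below the number reached by chance. Under permutation at 0.05 over all regions, stem and progenitor losses were 0.981 times the chance number, and 0.919 at matched abundance, both near chance and not called. Stem and progenitor gains were 0.435 and 0.415 times it, turned and called. Chromatin modifier losses were 0.546 at matched abundance, turned and called. Protein-coding genes gave 3 list tests. Away from gene ends 4 chromosomes were called. The cause of the other changes was not tested. The fold difference at gene ends stayed called, at 0.35 in the wider regions against 0.21 in all. Spi1 and Tet2 kept their counts of changed regions with 20 kb in place of 100 kb on either side, the only alternative run for them. At an adjusted p under 0.05, 19 regions within 100 kb of Spi1 and 2 within 100 kb of Tet2 passed.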

Other observations

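All tests in this part were chosen after the results were seen. At Runx1, looked at because it had changes in both directions, 6 of 56 tested regions changed, and no relation to position was tested. In the authors' deposited table the 4 gains lay between 92608067 and 92698905 on chromosome 16, from 1.71 to 2.70. The 2 losses lay at 92800732 to 92802218 and 92821614 to 92822645, at -1.95 and -1.96 in the authors' deposited table. On chromosome 14 the gain at Mcpt8, starting at 56084950, lay beside the gains at Ctsg, starting at 56099041 and 56100659, in the authors' deposited table.

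Zcchc14, a zinc finger gene on chromosome 8, had 4 gains, and the region at its end reached 3.61 (adjusted p = 7.23e-09) in the authors' deposited table. Lifr, the receptor gene for leukemia inhibitory factor, and Asb2, a ubiquitin ligase subunit gene of myeloid cells, had 4 losses each. Those of Lifr ran from -2.44 to -3.83 and those of Asb2 from -2.31 to -4.28 in the authors' deposited table.

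The stretch of chromosome 2 from 53.7 to 158.2 Mb was lower by about the amount that halving a template would give. Normalization of whole libraries would act on the other chromosomes as well and is argued against: their most abundant gene-end regions had a median of 0.18 and a lower quartile of -0.27. Closing of distal elements alone is argued against by the same class of regions in the stretch, with a median of -0.93 and an upper quartile of -0.69. Loss of 1 of 2 DNA copies may account for it: over 10 classes of abundance and location the median nearest to 0 was -0.79, a value judged by a bound set once the shift was known. The stretch stood at -1.09 against the rest of the chromosome, where a loss in only some of the leukemic libraries compared would give a smaller shift, and genomic read depth per mouse would test it.

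The 2 regions where the URE lies fell much further than the stretch around them. An intact URE copy that stayed as open as before is argued against, since the weaker of the 2 values was -6.21. A candidate explanation is that the leukemic cells had no URE DNA left, through loss of the chromosome 2 stretch carrying the intact copy, with -7.30 as the lower value. The table holds no measure of DNA amount, so absent DNA and closed chromatin at an intact copy cannot be told apart. Genotyping the URE in sorted leukemic cells would separate them.

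Chromosome X was lower by less and unevenly. Loss of an active X copy in leukemic cells could not be decided by the 764 most abundant regions of the chromosome. Their median was -0.17, above the -0.99 of the chromosome 2 stretch, but quartiles of -0.86 and 0.32 left too wide a spread. Loss in all or only some cells or libraries stays open. The lowest region in Xist, the RNA gene that silences an X copy, stood at -4.72 but with an adjusted p of 0.0756 in the authors' deposited table, so a different share of female mice on the 2 sides stays open. Loss of the inactive X copy in leukemic cells would lower Xist and the 765 least abundant regions, with a median of -0.58, in the same way, and the 2 cannot be told apart without the sex of each mouse.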
